A study of Sus scrofa with 8 samples.

How the data were processed

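Polyadenylated RNA from the endometrium of 8 gilts, crossbreeds of German Landrace and Piétrain, was sequenced. Per the labels' protocols, ovulation was synchronised with 750 IU PMSG and, 72 h later, 750 IU hCG, gilts were inseminated 24 h and 36 h after hCG, and tissue was taken on day 12 after the uteri had been flushed. The controls received the supernatant of centrifuged semen of the same boar. RNA of 3 sites of one uterine horn was pooled per animal, and RNA integrity numbers ranged from 7.9 to 9.5. Libraries were made from 5 µg total RNA with random priming, size selection at 200 ± 25 bp and 15 cycles of PCR, with no step that marks the strand, per the labels' protocols. Reads therefore cannot be assigned to a strand, and genes whose exons overlap a gene on either strand are marked as uncertain where they are named.

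The authors deposited raw read counts per transcript in whole numbers, 1 table per animal. CASAVA 1.6, TopHat 1.4, Cufflinks 1.3 and DESeq are named with the build Sscrofa10.2 in the submitters' processing notes and the deposited settings. These settings allowed up to 5 alignments per read, so a read can count for several similar genes. The tool that counted reads per transcript is not given in the sources used here. The deposited annotations gave the coordinates, which are on Sscrofa10.2.

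The tables held 24140 transcript rows with an Entrez gene identifier each, and counts were summed to 21063 genes. Of these, 19215 had 1 row and 1848 had several. Rows of one gene were often nearly equal in counts, so a summed gene can hold the same reads more than once and its CPM is then too high. Fold changes were therefore also computed with only the row of the highest mean count per gene. Symbols were taken from a RefSeq gene table of the assembly Sscrofa11.1, whose coordinates were not used, matching 16270 genes by identifier and 103 by transcript accession. The other 4690 genes, with 14.7% of the reads, kept their identifiers. The third planned count, of features outside annotated genes, had no such features, so it was made on the 642 rows of isoforms added by the authors' assembly.

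Samples were grouped by their titles, 4 pregnant and 4 control animals, each a different animal per the series' design text. No pair of libraries of one group agreed within sampling noise. Genes were filtered with filterByExpr at its minimum count of 10, which left 16633, and normalised by TMM. Groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 29.0%. The 27 gene lists, the tests and the rule for named genes were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. CPM values use TMM-scaled library sizes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

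Genes were named by a fixed rule. It took the 12 largest rises and 8 largest falls among called genes with a symbol other than a LOC number, non-overlapping groups and a mean count of at least 50 in the higher group. It added the 5 called genes with the highest mean CPM, up to 4 called members of each list with the smallest adjusted p (or the 2 members with the highest CPM in a list with none called), and a fixed set of genes of interest. MMP8 in the neutrophil list and the lower members of the calcium list fall outside the rule and were named after its values were seen.

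Total counts were 46384238 to 55294170 per library. Low counts came mostly in even numbers: over the 8 libraries, 4500 rows had 2 reads, 1010 had 1 read and 887 had 3 reads. Counting intervals at 95% and the floor of 3 reads over a group cover counting error only, and are too narrow where reads were counted more than once or copied by PCR. On simulated counts of 16633 genes for this comparison, the procedure recovered 3.98% of genes changed 1.5-fold, 33.3% changed 2-fold and 92.4% changed 4-fold, and 6.86% of its calls were false. Only a small share of the simulated genes was changed, against 38.1% of tested genes called in the data. Benjamini-Hochberg adjustment is stricter when few genes change, so these rates need not hold for the real comparison. In the same simulations camera called 3 of 3 planted lists and 0 of 78 unchanged lists. Genes were simulated as independent of each other, whereas the estimated correlation was 0.717 in the cell cycle list and 0.737 in the ciliated cell list. The simulations therefore do not show how camera with the preset correlation behaves on correlated lists.

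Alternatives were RLE and upper quartile normalization, no filter on low counts, a CPM of at least 1 in 4 libraries, DESeq2 1.42.0, a robust fit, the replicate number as a block, each library left out in turn, an adjusted p under 0.01 and annotated transcripts alone. Using 1 row per gene and thinning all libraries to the smallest total of 46384238 were added after the data were seen.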

Results

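RNA was sequenced from the endometrium, the inner lining of the uterus, of 8 gilts (young female pigs) at day 12 after insemination. Ovulation had been synchronised with gonadotropins, and 4 gilts were inseminated with semen and were pregnant, while 4 controls received semen supernatant. Each library was one animal, with RNA of the distal, medial and proximal parts of one uterine horn pooled. Day 12 lies in the period in which pig conceptuses elongate and secrete estrogen, and the comparison asks how the endometrial transcriptome of pregnant gilts differs from that of cyclic controls. Total counts were 46384238 to 50043246 in the 4 control libraries and 50959725 to 55294170 in the 4 pregnant libraries, so that every pregnant library was deeper than every control library. In all, 21063 genes were listed, and between 18033 and 18214 of them had at least 1 read in a library. Fold changes below are log2 of pregnant over control ± SE with n = 4 per group, and levels are mean CPM (read counts scaled to the library's normalised size) ± SD with n = 4. The SE was derived from the test, as the unshrunken log2 fold change over the square root of the F value. The printed fold changes are shrunken by a small prior count, most for genes with few reads in a group, so their SE is approximate. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. Coordinates refer to the Sscrofa10.2 build.

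Pregnant and control endometrium differed in 6345 of 16633 tested genes, with 3159 genes higher and 3186 lower in pregnant animals. Of the called genes, 2762 differed at least 2-fold, 1500 of them higher and 1262 lower. In 6034 of the 16633 tested genes all 4 libraries of one group lay above all 4 of the other, an arrangement that chance gives for 2.86% of genes. The first principal component held 58.3% of the variance and separated the groups. The second held 13.6% and set pregnant replicate 3 apart from pregnant replicate 2, with scores of 70.1 and -42.9. Spearman correlations across genes were 0.971 to 0.991 within groups and 0.950 to 0.963 between groups. Without pregnant replicate 3, the test called 7265 genes, 3130 of them at least 2-fold changed. At an adjusted p under 0.01 it called 3246 genes.

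**Figure D1:**
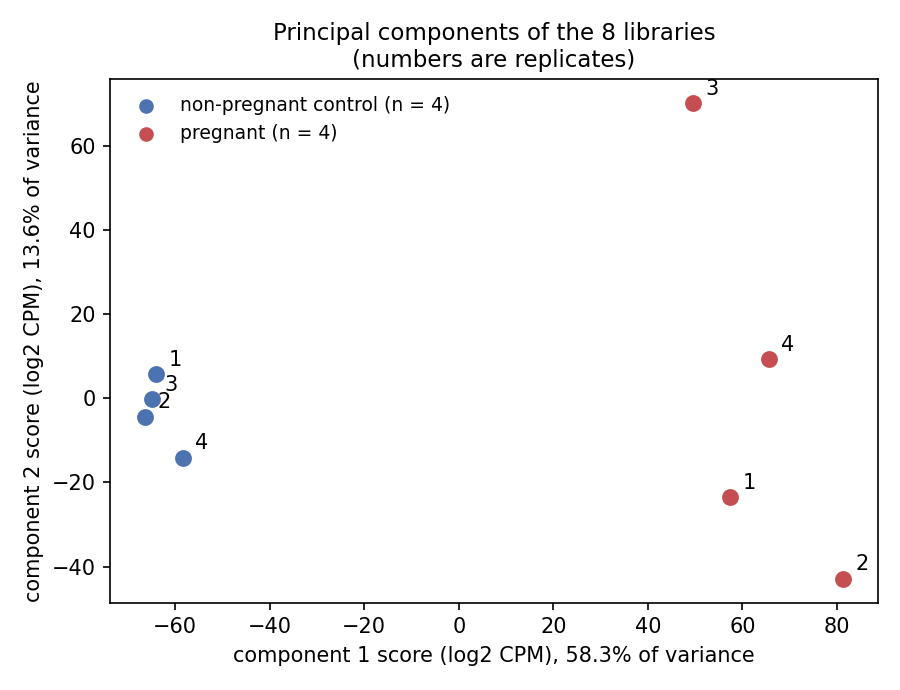
Scores of the 8 libraries on the first principal components of log2 CPM, with component 1 (58.3% of the variance) on the horizontal axis and component 2 (13.6%) on the vertical axis, and each point one animal. Control libraries lie on the left and pregnant libraries on the right, with pregnant replicate 3 at 70.1 on component 2.

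**Figure D2:**
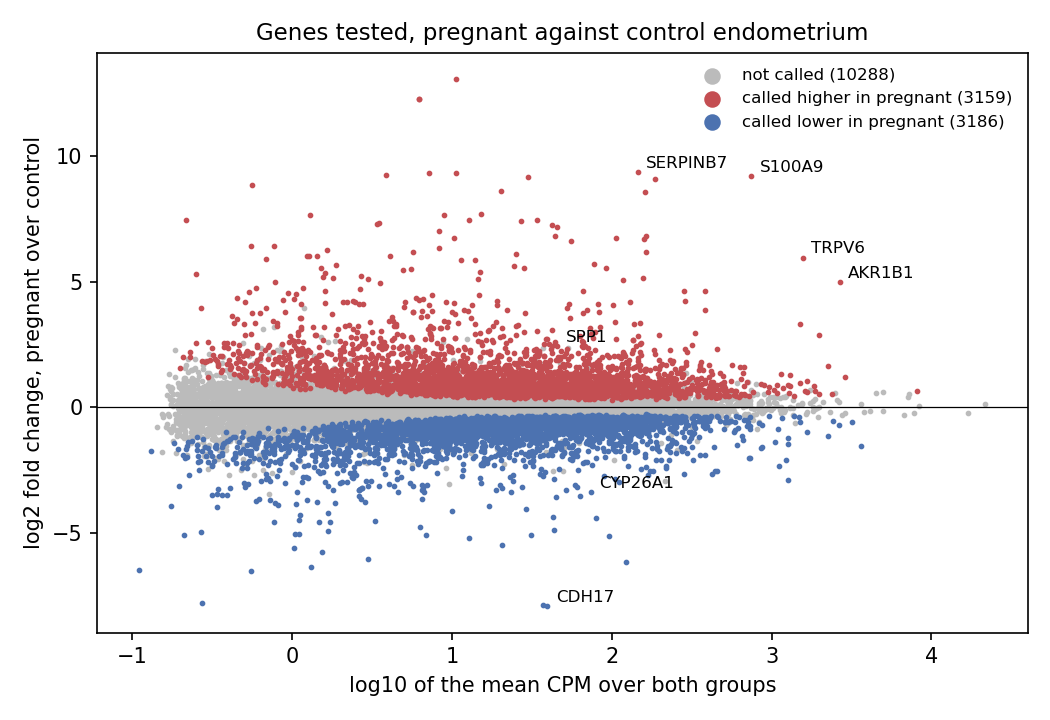
Log2 fold change of pregnant over control against the log10 of the mean CPM over both groups, with each point 1 of the 16633 tested genes. Of these, 3159 were called higher and 3186 lower at an edgeR adjusted p under 0.05.

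The largest rises were in genes that were close to silent in control endometrium. Osteocrin (OSTN, gene ID 100049691, chromosome 13, 137926852 to 137969821) had 0 reads over the control libraries and 21.2 ± 14.0 CPM in pregnant libraries, at least 1400.5-fold higher when the controls are set to a floor of 3 reads over the group. The serpin SERPINB7 (gene ID 100152588, chromosome 1, 175390357 to 175435316), whose value sums 3 transcript rows, rose from 0.435 ± 0.526 to 289.7 ± 164 CPM (9.38 ± 0.86, adjusted p = 9.65e-05). The neuropeptide NPY rose from 6 reads over the control libraries to 21.1 ± 12.4 CPM (9.33 ± 0.77, adjusted p = 5.21e-05). The calcium-binding S100A9 (gene ID 100127489, chromosome 4, 105063476 to 105066297) rose from 2.50 ± 3.40 to 1489.6 ± 422 CPM (9.22 ± 1.12, adjusted p = 4.18e-04), and its partner S100A8 (chromosome 4, 105091815 to 105092333) from 0.692 ± 1.06 to 374 ± 87.4 CPM (9.07 ± 1.02, adjusted p = 2.80e-04). S100A12 and S100A7, from the same stretch of chromosome 4, rose with log2 fold changes of 8.59 ± 0.74 and 7.35 ± 1.17. The remaining members of the 12 largest rises were SERPINB2 at 8.61 ± 1.84, SERPINB11 at 7.66 ± 0.62, the acute-phase gene SAA3 at 7.25 ± 0.51, the peptide transporter SLC15A1 at 7.17 ± 0.61 and the ammonium transporter RHBG, which rose from 0.127 ± 0.0734 to 16.6 ± 13.8 CPM. Single libraries set the size of several rises. SERPINB2 stood at 153 CPM in pregnant replicate 2 and at 1.07 to 4.38 CPM in the other pregnant libraries, and its log2 fold change was 4.95 without that library. Without control replicate 4, the log2 fold changes were 10.80 for S100A9, 11.12 for S100A8, 8.80 for S100A7, 10.68 for SERPINB7 and 7.90 for SLC15A1. S100A7 had 6.49 without pregnant replicate 1, NPY 10.39 without control replicate 3, and RHBG 6.30 without pregnant replicate 3. These calls held in each of those fits.

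The largest falls led to levels close to 0 in pregnant endometrium. The cadherin CDH17 (gene ID 100157834, chromosome 4, 45933342 to 46015800) fell from 78.9 ± 36.2 to 0.320 ± 0.284 CPM (-7.94 ± 0.63, adjusted p = 4.67e-05), and the orphan receptor gene GPR83 (gene ID 100513220, chromosome 9, 30305752 to 30318182) from 73.9 ± 38.3 to 0.313 ± 0.152 CPM (-7.87 ± 0.54, adjusted p = 2.14e-05). A beta-defensin gene, DEFB1 (gene ID 404699, chromosome 15, 43346358 to 43356952), fell from 242 ± 27.6 to 3.34 ± 0.994 CPM (-6.18 ± 0.25, adjusted p = 1.51e-06). GP2 had 222 reads over the control libraries and 2 over the pregnant libraries, a ratio of 0.00859 with a 95% counting interval of 0.00103 to 0.0314. CES5A, the hormone gene CCK, MGAT5B and BAALC had log2 fold changes of -6.36 ± 0.59, -6.06 ± 1.26, -5.78 ± 0.67 and -5.62 ± 0.75. CCK stood at 19.4 CPM in control replicate 4 and at 0.663 to 1.91 CPM in the other controls, and had -3.97 without that library and -7.15 without pregnant replicate 1. GP2 had -5.55 without control replicate 2 and -8.78 without pregnant replicate 1, while without pregnant replicate 2 BAALC had -7.04 and CDH17 -8.74. Among the 5 called genes with the highest mean CPM, AKR1B1, COL4A1 and RPS24 were higher in pregnant animals, and ATP1A1 and NDRG4 were lower. The collagen gene COL4A1 rose from 1756 ± 477 to 3981 ± 821 CPM (1.18 ± 0.22, adjusted p = 0.00324). RPS24, a ribosomal protein gene whose value sums 17 transcript rows, rose from 6340.1 ± 576 to 9790.2 ± 1274 CPM. NDRG4, whose value sums 4 rows, fell from 3799 ± 162 to 2539.8 ± 249 CPM. Summed rows can hold the same reads more than once, so the rank of these genes by CPM is uncertain.

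**Figure D3:**
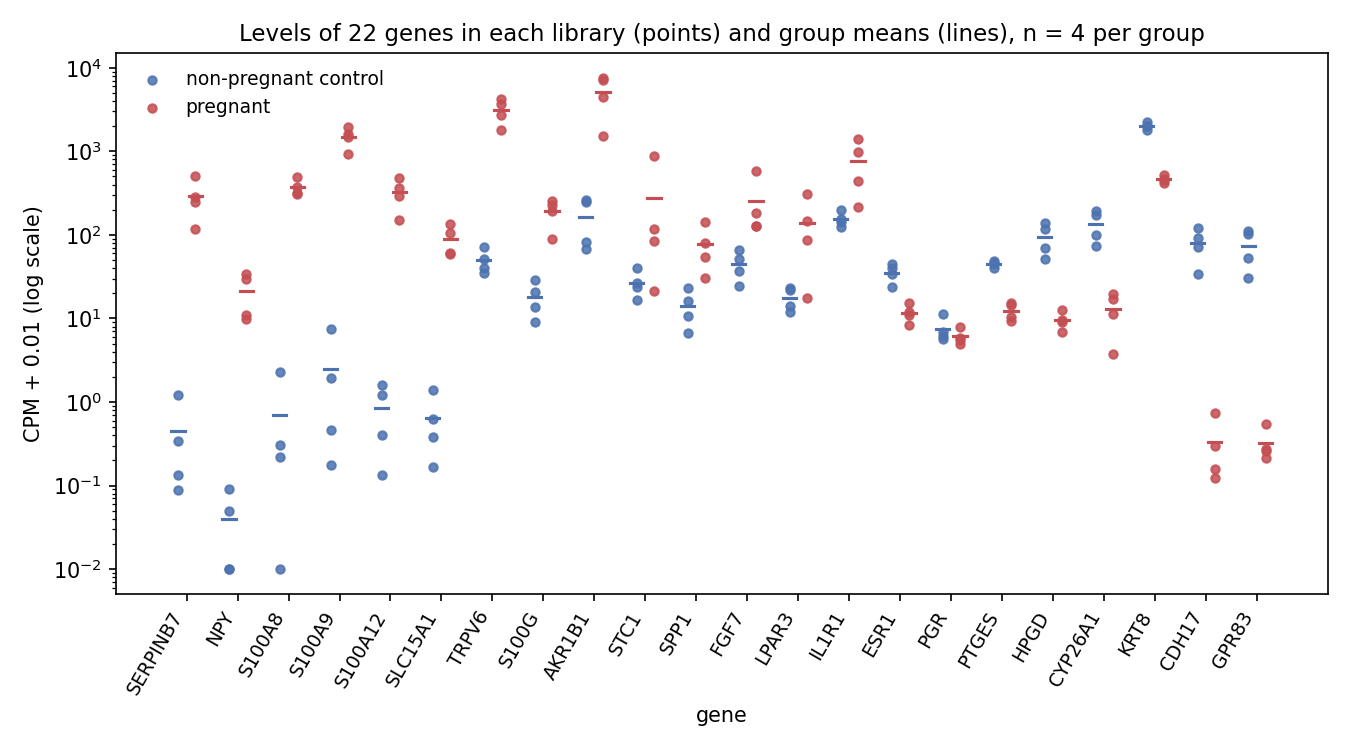
CPM + 0.01 on a log axis for 22 genes in each of the 8 libraries (points) with the mean of each group of 4 (lines), controls in blue and pregnant animals in red. S100A9 averaged 1490 CPM in pregnant and 2.50 CPM in control libraries, and KRT8 averaged 464 and 2011 CPM.

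Among genes of estrogen response and steroid receptors, 9 of 17 tested members were higher and 2 lower in pregnant animals (9 and 2 adjusted over the list alone). The aldo-keto reductase AKR1B1, an enzyme with prostaglandin F synthase activity (gene ID 396816, chromosome 18, 15596805 to 15614672), rose from 165 ± 106 to 5188 ± 2792 CPM (4.97 ± 0.65, adjusted p = 6.30e-04). The membrane mucin MUC4 rose by a log2 fold change of 3.32 ± 0.41, and the estrogen-responsive genes SPP1 (osteopontin) and FGF7 by 2.44 ± 0.50 and 2.52 ± 0.53. The lysophosphatidic acid receptor LPAR3 rose from 17.8 ± 5.73 to 140.2 ± 124 CPM (2.98 ± 0.68, adjusted p = 0.00833), but stood at 17.6 CPM in pregnant replicate 3, within the control range. Stanniocalcin (STC1) averaged 273 ± 399.5 CPM in pregnant and 26.7 ± 10.1 CPM in control libraries (3.35 ± 0.96, adjusted p = 0.0221), with 869 CPM in pregnant replicate 3 and 21.1 to 117 CPM in the others. The log2 fold change of STC1 was 1.48 without pregnant replicate 3, and its edgeR adjusted p was 0.0563, 0.0584 and 0.0559 without control replicates 1, 3 and 4. Without pregnant replicate 2, FGF7 had 1.72 and LPAR3 2.25. The estrogen receptor ESR1 fell from 35.4 ± 9.02 to 11.7 ± 2.85 CPM (-1.60 ± 0.24, adjusted p = 0.00105). The progesterone receptor PGR did not pass the test, at 7.48 ± 2.49 CPM in control and 6.08 ± 1.32 CPM in pregnant libraries (-0.30 ± 0.25, adjusted p = 0.371). As a set, the list did not pass camera, which compares a list with all other genes, at an adjusted p of 0.180.

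Genes of prostaglandin synthesis, transport and receptors moved both ways. Of this list, 5 of 21 tested members were higher and 4 lower in pregnant animals (7 and 4 adjusted over the list alone). Besides AKR1B1, the prostaglandin reductase PTGR1 rose from 1.71 ± 0.325 to 15.1 ± 3.82 CPM (3.14 ± 0.24, adjusted p = 4.24e-05). HPGD, which inactivates prostaglandins, fell from 93.8 ± 40.8 to 9.48 ± 2.26 CPM (-3.31 ± 0.33, adjusted p = 1.54e-04), and the prostaglandin E synthase PTGES from 45.1 ± 3.77 to 12.4 ± 2.92 CPM (-1.86 ± 0.18, adjusted p = 1.31e-04). PTGS2, the inducible cyclooxygenase, had 85.3 ± 19.6 CPM in control and 51.5 ± 38.8 CPM in pregnant libraries and did not pass the test (-0.73 ± 0.49, adjusted p = 0.267). The camera adjusted p was 0.746.

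Genes of calcium handling moved both ways. Of this list, 9 of 19 tested members were higher and 5 lower in pregnant animals (9 and 6 adjusted over the list alone), and the camera adjusted p was 0.180. TRPV6, an epithelial calcium channel (gene ID 100171400, chromosome 18, 7636964 to 7652620), rose from 49.6 ± 15.9 to 3095 ± 1068 CPM (5.96 ± 0.36, adjusted p = 1.05e-05), with 2.1% of its exon length overlapped by EPHB6. Its neighbour and relative TRPV5 (chromosome 18, 7540628 to 7548612) rose by a log2 fold change of 6.20 ± 0.50, the calcium-binding S100G by 3.40 ± 0.42, and the parathyroid hormone-like gene PTHLH by 3.23 ± 0.21. TRPV5 averaged 321 CPM in pregnant libraries, and its levels ordered the libraries of each group as those of TRPV6 did. With several alignments allowed per read, TRPV6 reads counted for TRPV5 cannot be told apart from a separate rise. The 5 lower members, named after their values were seen, were the exchangers SLC24A4 (-1.58 ± 0.28) and SLC8A1 (-0.65 ± 0.16), the calcitonin receptor CALCR (-1.64 ± 0.35), RAMP3 (-1.20 ± 0.35) and the vitamin D receptor VDR (-1.56 ± 0.51). VDR lost its call without control replicate 2 (-0.85, adjusted p = 0.108) and without pregnant replicates 1 and 4 (0.0693 and 0.0911), and RAMP3 without control replicates 1 and 2 and pregnant replicate 4 (0.0585, 0.0695 and 0.0662). Among transporters of glucose, amino acids and ions, 9 of 42 tested members were higher and 7 lower in pregnant animals (9 and 7 adjusted over the list alone), with a camera adjusted p of 0.859. The sodium pump subunits ATP1A1 and ATP1B1 fell from 5374 ± 489 to 1822 ± 376 CPM (-1.56 ± 0.16, adjusted p = 1.93e-04) and from 111 ± 5.41 to 24.5 ± 9.85 CPM (-2.18 ± 0.24, adjusted p = 2.80e-04). The glucose transporter SLC2A8 fell by 0.96 on the log2 scale, with an SE of 0.11. Of the genes of lipid mediator signalling, 6 of 21 tested members were higher and 4 lower in pregnant animals (7 and 5 adjusted over the list alone). LPAR6 and the sphingosine-phosphate lyase SGPL1 rose, with log2 fold changes of 1.07 ± 0.17 and 0.88 ± 0.14, while LPAR2 and PPARA had -1.53 ± 0.15 and -0.99 ± 0.20. That list had a camera adjusted p of 0.746, with a median of -0.0518 and a mean of 0.18 on the log2 scale.

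Of genes of interleukin-1, LIF and NF-kB signalling, 9 of 30 tested members were higher and 3 lower in pregnant animals (9 and 3 adjusted over the list alone), with a camera adjusted p of 0.132. The interleukin-1 receptor IL1R1 rose from 154 ± 31.0 to 763 ± 540.0 CPM (2.31 ± 0.49, adjusted p = 0.00607), and the decoy receptor IL1R2 from 0.152 ± 0.0693 to 11.3 ± 9.47 CPM (6.20 ± 0.81, adjusted p = 6.08e-04). IL6R rose by a log2 fold change of 2.02 ± 0.33, and IL11RA had -1.87 ± 0.27. Interleukin-1 beta (IL1B) had 25 reads over the control and 74 over the pregnant libraries and did not pass the test (adjusted p = 0.111). Of the interferon-stimulated genes, 3 of 35 tested members were higher and 12 lower in pregnant animals (3 and 13 adjusted over the list alone). IFITM3 fell from 257 ± 52.1 to 46.4 ± 6.31 CPM (-2.47 ± 0.18, adjusted p = 2.89e-05), MX1, an antiviral GTPase, from 269.5 ± 91.9 to 87.4 ± 14.8 CPM (-1.62 ± 0.24, adjusted p = 0.00119), and IFI44 by 0.98 on the log2 scale. IRF2 rose by a log2 fold change of 0.97 ± 0.15. The list was lower as a set (camera adjusted p = 0.0137), with adjusted p = 0.738 with an estimated correlation, and adjusted p = 0.0676 without pregnant replicate 1. Among genes of antigen presentation, 8 of 22 tested members were higher and 0 lower in pregnant animals (8 and 0 adjusted over the list alone). The class II genes SLA-DRA and SLA-DRB1, the class I gene SLA-6 and the protease CTSS rose, with log2 fold changes of 1.04 ± 0.16, 0.91 ± 0.20, 0.64 ± 0.12 and 0.82 ± 0.16. SLA genes form a family of similar sequences, so the split of reads between its members is uncertain. As a set the list was higher (camera adjusted p = 0.0149), with adjusted p = 0.738 with an estimated correlation, and adjusted p = 0.149 without pregnant replicate 3.

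**Figure D4:**
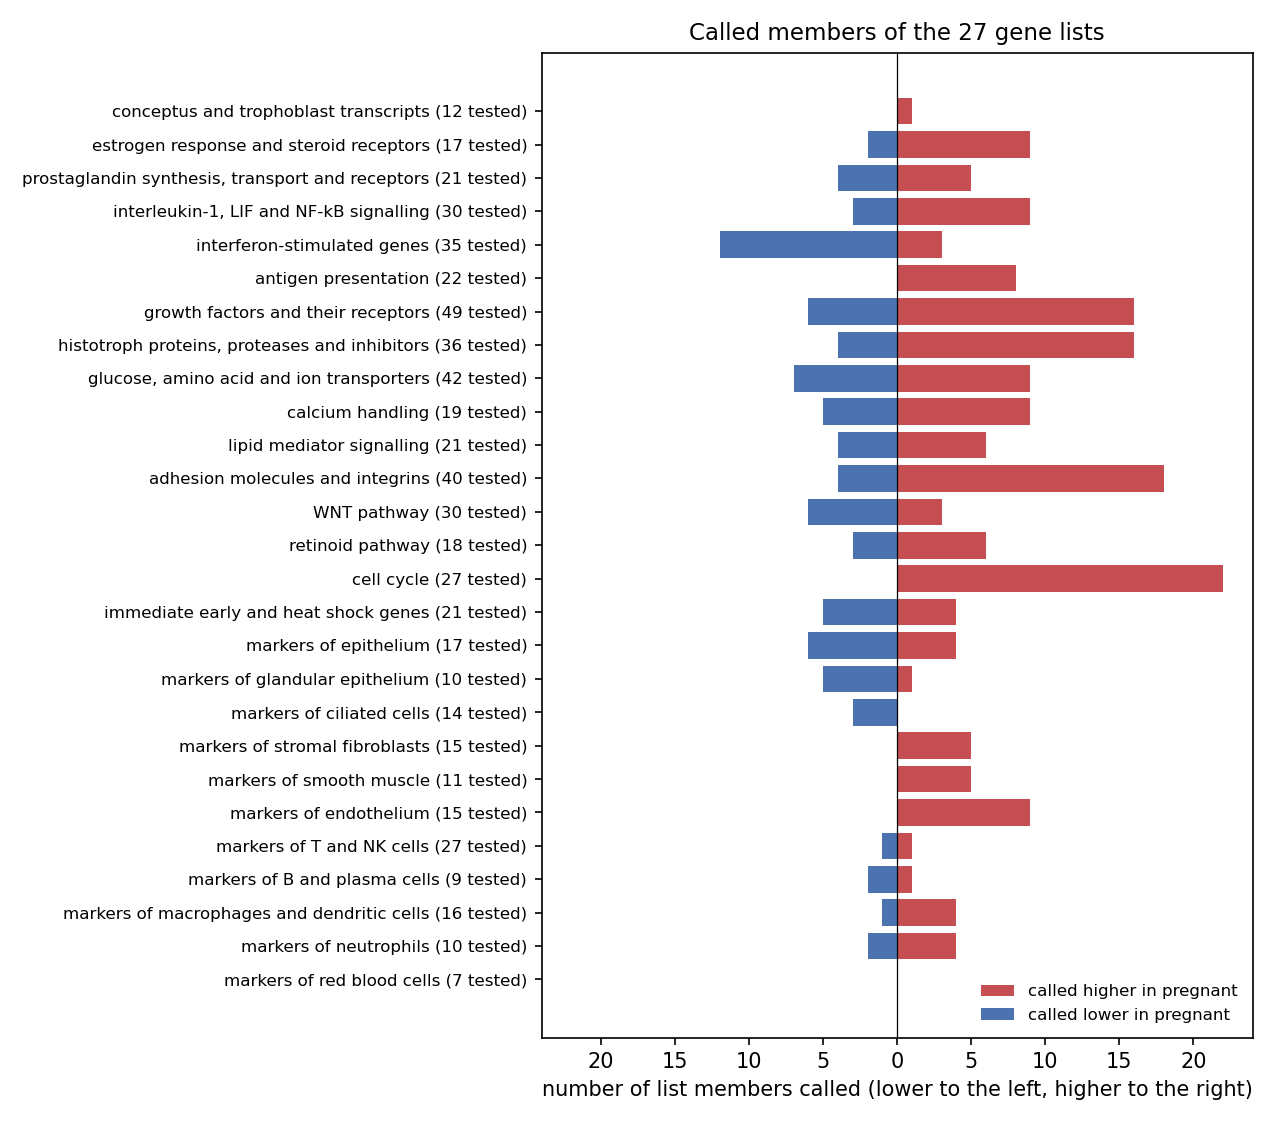
Number of members called lower (left, blue) and higher (right, red) in pregnant endometrium for each of the 27 gene lists, with the number of tested members in brackets. In the cell cycle list 22 of 27 tested members were higher and 0 lower, and in the list of interferon-stimulated genes 12 of 35 were lower and 3 higher.

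Growth factors and their receptors changed in both directions, and 16 of 49 tested members were higher and 6 lower in pregnant animals (17 and 7 adjusted over the list alone). FGF9 rose from 3.40 ± 0.601 to 26.6 ± 8.74 CPM (2.97 ± 0.26, adjusted p = 7.39e-05), the hepatocyte growth factor receptor MET from 17.4 ± 3.55 to 87.0 ± 4.46 CPM (2.33 ± 0.17, adjusted p = 2.88e-05), and FGF18 fell from 5.04 ± 0.572 to 0.393 ± 0.156 CPM (-3.67 ± 0.32, adjusted p = 6.99e-05). The camera adjusted p of the list was 0.180. Of histotroph proteins, proteases and inhibitors, which enter the uterine secretion, 16 of 36 tested members were higher and 4 lower in pregnant animals (17 and 4 adjusted over the list alone). The cathepsin CTSC rose from 36.9 ± 5.05 to 235 ± 40.6 CPM (2.67 ± 0.17, adjusted p = 1.35e-05), UABP-2 from 29.1 ± 17.1 to 549 ± 90.4 CPM (4.24 ± 0.46, adjusted p = 2.45e-04), and the metalloprotease MMP7 by a log2 fold change of 5.11 ± 0.58, or 4.52 without pregnant replicate 3. That list was higher as a set (camera adjusted p = 0.00846), with adjusted p = 0.581 with an estimated correlation. Among adhesion molecules and integrins, 18 of 40 tested members were higher and 4 lower in pregnant animals (18 and 5 adjusted over the list alone). The tight junction gene CLDN1 rose from 2.07 ± 0.996 to 24.2 ± 8.43 CPM (3.55 ± 0.39, adjusted p = 2.52e-04), and the integrins ITGB6 and ITGAV by log2 fold changes of 2.74 ± 0.29 and 1.78 ± 0.22. LAMB3 had 6.08 ± 0.51, but 100% of its exon length is overlapped by another gene, so its reads cannot be assigned with certainty. The list was higher as a set (camera adjusted p = 0.00804), with adjusted p = 0.581 with an estimated correlation.

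In the WNT pathway, 3 of 30 tested members were higher and 6 lower in pregnant animals (2 and 5 adjusted over the list alone), and the camera adjusted p was 0.207. WNT7A had a log2 fold change of -3.14 ± 0.42 (adjusted p = 7.13e-04). WNT5A and the receptor FZD6 had log2 fold changes of -1.02 ± 0.18 and -0.98 ± 0.12, and FZD4 had 0.79 ± 0.15. Of the retinoid pathway, 6 of 18 tested members were higher and 3 lower in pregnant animals (6 and 4 adjusted over the list alone), with a camera adjusted p of 0.708, a median of 0.22 and a mean of -0.0270 on the log2 scale. CYP26A1, which degrades retinoic acid, fell from 135 ± 57.5 to 13.0 ± 7.15 CPM (-3.38 ± 0.51, adjusted p = 0.00117). The retinol carrier RBP4 rose from 474 ± 250.4 to 3468 ± 979.8 CPM (2.87 ± 0.38, adjusted p = 6.50e-04), the retinol transporter STRA6 by a log2 fold change of 1.41 ± 0.25, and the retinal reductase DHRS3 by 1.61 ± 0.22.

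Of the cell cycle genes, 22 of 27 tested members were higher and 0 lower in pregnant animals (22 and 0 adjusted over the list alone). The kinetochore genes CENPF and CENPE rose from 3.65 ± 1.28 to 30.7 ± 9.77 CPM (3.07 ± 0.35, adjusted p = 2.95e-04) and from 2.81 ± 0.543 to 14.4 ± 3.49 CPM (2.36 ± 0.23, adjusted p = 1.34e-04). Cyclin B1 (CCNB1) and the kinesin KIF23 rose by log2 fold changes of 2.39 ± 0.29 and 2.60 ± 0.32. The list was higher as a set (camera adjusted p = 2.25e-09), with adjusted p = 0.581 with an estimated correlation. Of the immediate early and heat shock genes, which can respond to tissue handling, 4 of 21 tested members were higher and 5 lower in pregnant animals (4 and 5 adjusted over the list alone). FOS fell from 38.7 ± 5.69 to 13.6 ± 7.32 CPM (-1.51 ± 0.33, adjusted p = 0.00659), IER2 and KLF4 had log2 fold changes of -0.95 ± 0.15 and -0.95 ± 0.23, and the co-chaperone BAG3 had 0.76 ± 0.13. That list had a camera adjusted p of 0.746, with a median of 0.0637 and a mean of -0.0291 on the log2 scale.

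Markers of epithelium did not move in one direction, and 4 of 17 tested members were higher and 6 lower in pregnant animals (5 and 7 adjusted over the list alone). The keratins KRT8, KRT18 and KRT19 fell, KRT8 (gene ID 100152077, chromosome 5, 18663338 to 18671192) from 2011 ± 172 to 464 ± 46.3 CPM (-2.12 ± 0.13, adjusted p = 1.12e-05), KRT18 from 423 ± 35.3 to 125 ± 23.7 CPM and KRT19 from 487 ± 65.7 to 77.7 ± 43.2 CPM. The membrane protease ST14 rose from 229.7 ± 39.3 to 452 ± 80.4 CPM (0.98 ± 0.17, adjusted p = 0.00235). The camera adjusted p was 0.641, with a median of 0.0608 and a mean of -0.25 on the log2 scale. Among glandular markers, 1 of 10 tested members were higher and 5 lower in pregnant animals (2 and 5 adjusted over the list alone) (camera adjusted p = 0.504). MSX1, PIGR and FOXA2 fell, with log2 fold changes of -2.24 ± 0.21, -1.70 ± 0.27 and -1.22 ± 0.31, and RBP4 rose. Among ciliated cell markers, 0 of 14 tested members were higher and 3 lower in pregnant animals (0 and 0 adjusted over the list alone) (camera adjusted p = 0.0416, and adjusted p = 0.786 with an estimated correlation). CAPS, with 5.6% of its exon length overlapped by RANBP3, TPPP3 and DNAH9 had log2 fold changes of -1.20 ± 0.37, -0.64 ± 0.20 and -0.87 ± 0.29. Each of these calls was lost in several fits without 1 library, with edgeR adjusted p up to 0.0788, 0.0990 and 0.0997. The set call of the ciliated markers was lost without control replicates 1 and 2 and without pregnant replicates 2, 3 and 4 (adjusted p = 0.0591, 0.0540, 0.117, 0.176 and 0.0549), and kept without control replicate 3 or 4 and without pregnant replicate 1 (2.11e-05), which had the highest CAPS and DNAH9 levels of its group (34.8 and 13.8 CPM).

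Of the endothelial markers, 9 of 15 tested members were higher and 0 lower in pregnant animals (9 and 0 adjusted over the list alone). KDR rose from 111 ± 14.7 to 279 ± 44.7 CPM (1.33 ± 0.16, adjusted p = 3.54e-04), PECAM1 from 94.4 ± 16.4 to 220.2 ± 21.1 CPM (1.22 ± 0.15, adjusted p = 4.70e-04), and TEK and ERG by log2 fold changes of 1.14 ± 0.16 and 0.94 ± 0.14. The camera adjusted p was 0.00804, and adjusted p = 0.581 with an estimated correlation. For smooth muscle, 5 of 11 tested members were higher and 0 lower in pregnant animals (5 and 0 adjusted over the list alone). ACTA2 and SYNM had log2 fold changes of 1.25 ± 0.32 and 0.92 ± 0.23, ACTG2 had 1.37 ± 0.42 and MYLK (gene ID 100152091) had 0.85 ± 0.23. The smooth muscle list had a camera adjusted p of 0.0492, and adjusted p = 0.645 with an estimated correlation. This call was also lost with RLE normalization (0.0519) and with 1 library left out, except without control replicate 4 or pregnant replicate 1, with adjusted p up to 0.108. ACTG2 lost its call without control replicates 1 and 2 and pregnant replicates 2 and 4 (adjusted p up to 0.0805), and MYLK without control replicate 1 or pregnant replicate 4 (0.0513 and 0.0523). For stromal fibroblasts, 5 of 15 tested members were higher and 0 lower in pregnant animals (6 and 0 adjusted over the list alone) (camera adjusted p = 0.132, and 0.0426 without control replicate 4). FAP and VIM had log2 fold changes of 0.94 ± 0.18 and 0.75 ± 0.18. THY1 had 2.93 ± 0.64, or 1.93 without pregnant replicate 3. PDGFRA had 0.51 ± 0.16 and lost its call without control replicates 1, 2 and 4 and pregnant replicates 2 and 4 (adjusted p up to 0.0831).

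Of the markers of T and NK cells, 1 of 27 tested members were higher and 1 lower in pregnant animals (0 and 0 adjusted over the list alone) (camera adjusted p = 0.774). KLRK1 had a log2 fold change of 0.94 ± 0.25, and IL2RB had -0.61 ± 0.21 with a call that was lost in every fit without 1 library except those without control replicate 2 or pregnant replicate 2 (adjusted p up to 0.114). For B and plasma cells, 1 of 9 tested members were higher and 2 lower in pregnant animals (1 and 2 adjusted over the list alone) (camera adjusted p = 0.641). MZB1 had -2.09 ± 0.32 and BLNK 1.53 ± 0.27, while JCHAIN had -1.08 ± 0.37 with adjusted p between 0.0523 and 0.101 without control replicates 3 and 4 and without any 1 pregnant library. For macrophages and dendritic cells, 4 of 16 tested members were higher and 1 lower in pregnant animals (4 and 3 adjusted over the list alone) (camera adjusted p = 0.606). CD14, LYZ, MSR1 and MRC1 rose, with log2 fold changes of 1.76 ± 0.27, 1.81 ± 0.32, 1.17 ± 0.28 and 0.80 ± 0.20. Of the markers of neutrophils, 4 of 10 tested members were higher and 2 lower in pregnant animals (4 and 2 adjusted over the list alone) (camera adjusted p = 0.431). Besides S100A8, S100A9 and S100A12, MMP8 rose from 16.4 ± 4.46 to 151 ± 163 CPM (3.21 ± 0.73, adjusted p = 0.00806), with 19.3 CPM in pregnant replicate 3, within the control range, and a log2 fold change of 2.14 without pregnant replicate 2, whereas ELANE, a protease of neutrophil granules, fell from 3.18 ± 0.374 to 1.43 ± 0.324 CPM (-1.15 ± 0.24, adjusted p = 0.00542). The markers of red blood cells had 0 called of 7 tested members in edgeR, 0 at an unadjusted p under 0.05 and 0 called in DESeq2 (camera adjusted p = 0.641). HBB had 379.6 ± 141 CPM in control and 329 ± 171 CPM in pregnant libraries, with 58.7% of its exon length overlapped by another gene, and HBZ had 247 ± 96.1 and 189.8 ± 100.3 CPM. The levels of HBZ ordered the libraries of each group as those of HBB did. With several alignments allowed per read, reads of similar globin genes counted for HBZ cannot be told apart from its own.

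Transcripts of the conceptus were looked for because the uteri had been flushed before sampling. Of this list, 1 of 12 tested members were higher and 0 lower in pregnant animals (1 and 0 adjusted over the list alone) (camera adjusted p = 0.708). The called member was CYP17A1, an enzyme of steroid synthesis, with 26 reads over the control and 101 over the pregnant libraries (1.86 ± 0.41, adjusted p = 0.00659). The other 10 listed members fell below the filter on low counts. They had 123 reads in pregnant replicate 3, 11 to 15 reads in the other pregnant libraries and 11 to 36 reads in the controls. NANOG alone gave 34, 7, 6 and 10 of these reads in control replicates 1 to 4, and 0, 3, 2 and 2 in pregnant replicates 1 to 4. IL1RAP, STAT1 and CYP19A1 were not listed under those symbols and were not analysed here.

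Assembled isoforms were tested on single transcript rows. All rows carried a gene identifier, so no feature lay outside the annotated genes, and the comparison covers isoforms that the authors' assembly added to 505 annotated genes. Of 619 tested isoforms, 263 were called between pregnant and control endometrium. The count was 120 at an adjusted p under 0.01. Near-equal counts of rows of one gene limit what these calls say of an isoform: of 1583 genes with at least 2 rows of mean count 100 or more, 1262 had their 2 largest rows within 10% of each other.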

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

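The tests of explanations in this part were chosen after the result was seen. In each group of 4 libraries, the gap of the most distant library to its nearest neighbour was divided by the range of the group, for the CPM of each named gene and for library measures. Of 246 groups, 24 had a ratio above Dixon's 95% critical value for 4 values. Chance gives about 1 in 20 for independent, normally distributed values. CPM of related genes need not be either, so an excess over chance is not shown. Control replicate 4 held 7 of these values, pregnant replicates 1 and 2 held 5 each, pregnant replicate 3 held 4, and control replicates 1 and 3 and pregnant replicate 4 held 1 each.

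Among controls, replicate 4 was high for S100A8 (2.27 CPM against at most 0.293, ratio 0.871), THY1 (23.8 CPM, ratio 0.902), MRC1 (14.9 CPM, ratio 0.853), KRT18 (476 CPM, ratio 0.874) and CCK (19.4 CPM against at most 1.91, ratio 0.933). It was low for ITGAV (22.3 CPM against at least 40.7, ratio 0.937) and RPS24 (5479 CPM, ratio 0.895). Control replicate 1 was high for PTHLH (4.95 CPM, ratio 0.887), and control replicate 3 for FZD6 (129 CPM, ratio 0.866). In pregnant animals, replicate 2 was high for SERPINB2 (153 CPM against at most 4.38, ratio 0.978), SAA3 (134 CPM, ratio 0.871), FGF7 (582 CPM against at most 184, ratio 0.874) and GPR83 (0.538 CPM, ratio 0.834) and low for IL11RA (35.9 CPM, ratio 0.889). Pregnant replicate 1 was high for the ciliated cell markers DNAH9 (13.8 CPM against at most 6.14, ratio 0.926) and CAPS (34.8 CPM against at most 13.1, ratio 0.888, exons overlapped in part by RANBP3), and for CCK (0.227 CPM, ratio 0.979) and GP2 (0.0378 CPM against 0, ratio 1). It was low for MSR1 (3.61 CPM, ratio 0.939). Pregnant replicate 4 was low for CES5A (0 CPM against at most 0.0412, ratio 0.916), a gap of very few reads. Pregnant replicate 3 was high for STC1 (869 CPM against at most 117, ratio 0.887), RBP4 (4930.0 CPM, ratio 0.899), IL6R (33.4 CPM, ratio 0.913) and NDRG4 (2909 CPM, ratio 0.865).

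Pregnant replicate 3 stood apart within its group. With 0.1 added to each CPM, 43 genes in it lay at least 4-fold above all other pregnant libraries and 61 at least 4-fold below, against at most 22 and 24 for any other pregnant library. The genes above included GPX3 (1144 CPM against at most 113), STC1 and NNAT (99.7 CPM against at most 8.20), and those below LPAR3 (17.6 CPM against at least 87.6), MMP8 (19.3 against at least 95.3) and ANXA8 (74.7 against at least 333), all picked after their values were seen. Library depth is argued against, since the other pregnant totals were at most 1.09 times as large, while thinning, which left 96.2% of these genes 4-fold apart, removed 8.98% of the library's reads and could hardly have ended the pattern. Added conceptus RNA is argued against for the genes below, since it would not put 61 genes 4-fold lower. For the genes above it cannot be told apart: this library held 75.5% of the pregnant libraries' reads of the low conceptus genes, among them IFNG (65 reads against at most 4) and IL1B2 (43 against at most 7), while 0 of the 12 tested members of the conceptus list were among the 43 genes. The filter asks for reads in several libraries. Conceptus genes read mainly in this library, such as IFNG and IL1B2, were therefore removed before the 43 genes were taken, which limits what the 0 of 12 can say. A difference between animals, such as the state of the conceptuses, stays open and was not tested.

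S100A8, S100A9 and S100A12 rose by at least 8.59 on the log2 scale and are abundant in neutrophils. The other 7 tested neutrophil markers had a median log2 fold change of -0.424 with an SD of 1.68, and 1 was called higher and 2 lower. Apart from MMP8, which rose by 3.21 on the log2 scale, none had a mean above 1.44 CPM in the pregnant group. As far as the markers of this list go, these values argue against neutrophils as the main source, while a smaller part played by them stays open. Apart from MMP8 the markers compared were low, and neutrophil genes outside the list were not used. Depth is argued against, since the highest library total was 1.19 times the lowest and the smallest rise of the 3 genes was 386-fold. These genes may have risen in a resident cell type of pregnant endometrium, a hypothesis that was not tested. Other immune cells as a source were not tested either.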

How the results depend on the processing

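The number of called genes lay between 4545 and 7265 when 1 library was left out, and that of genes changed at least 2-fold between 2421 and 3130, against 6345 and 2762, and that of assembled isoforms between 181 and 297, against 263. At an adjusted p under 0.01 there were 3246 genes and 120 isoforms, by construction. Other normalizations, filters, DESeq2, a robust fit, annotated transcripts alone, 1 row per gene and thinning (the last pair chosen after seeing the data) gave 6095 to 7233 called genes. With the replicate number as a block 4956 genes were called. Numbers were shared by different animals, whose deviations correlated by -0.0179, -0.0799, 0.0789 and -0.0912 for numbers 1 to 4, and for 1 of the 4 numbers the best partner carried the same number. The block ended the calls of STC1 (edgeR adjusted p = 0.125), KLRK1 (0.0542), PDGFRA (0.0569) and IL2RB (0.0816). It ended no other call of a list or of a gene named by the fixed rule. For genes named after their values were seen, the block was not examined. The stricter threshold ended calls of named genes by construction. Over the genes named by the fixed rule, 914 of the fits without 1 library kept direction and side of the threshold, 44 lost the call and 2 turned direction. Genes named after their values were seen are not in these counts. HBB, which was not called, ranged from -0.46 to 0.059 on the log2 scale and was above 0 without control replicate 4 (0.028) and pregnant replicate 1 (0.059).

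List values are camera adjusted p-values unless fry is named. With an estimated correlation none of the 8 list calls held: interferon-stimulated genes and antigen presentation had 0.738, histotroph, adhesion, cell cycle and endothelium 0.581, ciliated cells 0.786 and smooth muscle 0.645. By fry, which tests a list against no change and not against other genes, estrogen response (0.00114), interleukin-1 (0.00585), growth factors (0.0117), calcium handling (0.00233), WNT (0.00585), epithelium (0.0198), glandular epithelium (0.0499) and neutrophils (0.0375) passed, antigen presentation (0.0751) and ciliated cells (0.153) did not, and transporters turned downward (0.785). Smooth muscle was lost with RLE (0.0519), a CPM of at least 1 (0.0524) and 1 row per gene (0.0512), and neutrophils passed with a CPM of at least 1 (0.0454). At 0.01, interferon-stimulated genes (0.0137), antigen presentation (0.0149), ciliated cells (0.0416) and smooth muscle (0.0492) were no longer called. Without 1 library, adjusted p ranged from 0.00423 to 0.0676 for interferon-stimulated genes, 0.00420 to 0.149 for antigen presentation, 2.11e-05 to 0.176 for ciliated cells, 0.00476 to 0.108 for smooth muscle and 0.0426 to 0.280 for stromal fibroblasts. The direction turned in lists that were not called, with 0.689 to 0.984 for lipid mediators, 0.660 to 0.984 for transporters, 0.433 to 0.984 for T and NK cells and 0.380 to 0.938 for immediate early genes. Except for the stricter threshold, the cause of these changes was not tested. In simulations of genes at a mean CPM of at least 1, chosen after seeing the data, changes of 2-fold were recovered in 33.3% of genes at the real depth, 35.3% at 0.5 times and 35.3% at 2 times that depth, so that depth did not limit the calls in these simulations. Genes of fewer reads were not simulated with changes. Few genes were changed in these simulations, so the shares recovered need not hold for the data.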

Other observations

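The tests of explanations and the counts over splits in this part were set out after the results were seen, and the genes in the first paragraph were picked after their values were seen. Some neighbours of the large rises on chromosomes 4 and 1 rose too, while 19.0% of all tested genes were called higher by edgeR, and no excess was tested. Within 100 kb of the S100 genes S100A9, S100A12, S100A8 and S100A7, 2 of the 4 other tested genes were higher, PPGRP-S (log2 fold change 2.05 ± 0.36) and the peptidoglycan recognition gene PGLYRP3 (1.72 ± 0.53, lost without control replicate 1, 3 or 4 or pregnant replicate 2 or 4, with adjusted p up to 0.0779), while S100A16 (0.56 ± 0.22, passing without pregnant replicate 3 at adjusted p = 0.0125) and S100A14 (0.27 ± 0.27) did not pass the test. Within 100 kb of SERPINB11, SERPINB7 and SERPINB2, 3 of the 4 other tested genes were higher, among them LOC100153783, from 0.378 ± 0.130 to 67.6 ± 22.3 CPM. SERPINB10 in the same stretch did not pass the test (0.94 ± 0.62). Of the 7 tested water channel genes, 4 fell, AQP3 from 83.2 ± 22.4 to 6.91 ± 7.51 CPM (log2 fold change -3.59 ± 0.75, or -4.62 without pregnant replicate 1), AQP5 by 4.52 on the log2 scale, AQP6 by 3.51 (log2 fold change -4.39 without pregnant replicate 3) and AQP11 by 0.97. AQP8 (0.47 ± 0.51, or -0.32 without pregnant replicate 3), AQP9 (0.82 ± 0.88) and AQP10 (0.41 ± 0.30) did not pass the test, although AQP10 did without pregnant replicate 3 (adjusted p = 0.0415). The metalloprotease ADAMTS20 rose from 0.777 ± 0.369 to 87.2 ± 64.6 CPM.

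In a scan of 210 families of shared symbol stems for an excess of called genes, the keratins were the 1 family that passed, with 20 of 26 tested genes lower (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 2.50e-07 over 420 tests). KRT23 was the 1 keratin that rose, from 0.462 ± 0.303 to 27.3 ± 15.3 CPM (log2 fold change 5.87 ± 0.76). A smaller share of epithelium as a whole is argued against for KRT8, KRT18 and KRT19, because the other 14 tested epithelial markers had a median log2 fold change of 0.156 with an SD of 0.592, against falls of at least 1.76. Of these 14, 4 were called higher and 3 lower, and of 10 tested glandular markers 1 was higher and 5 lower. A smaller share of 1 part of the epithelium, such as the glands, stays open, since a median over all markers cannot show it. Reads shared with the other named keratins are argued against too, since those 17 genes held in controls 2.60% of the CPM that the 3 genes lost. For the 17 others, all at 8.40 CPM or less in controls, shared reads cannot be told apart from separate falls. Of them, 8 had a partner within 20% in every control library, against a median of 3 and a highest value of 10 in 1000 random sets of like expression, of which 18 reached 8. KRT1 and KRT2 had identical counts in every library, and KRT31, KRT33A and KRT34 in at least 6 of 8, so the family test counts genes that are not independent. With keratins equal in at least 6 libraries taken as 1 gene, 17 of 23 were lower (Fisher's exact p = 3.35e-08, unadjusted), and with all 17 low keratins taken as 1 gene, 4 of 10 were lower and the test did not pass (p = 0.117).

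The 35 splits of the 8 libraries into 4 and 4 argue against chance for the gene counts. A share of 1 of 35 is the smallest that they can reach. Every other split mixes pregnant and control animals, so the group difference adds to the spread within its groups and lowers its calls. The splits therefore add little to the separation of the groups already seen. The real groups gave 6345 called genes, 2762 of them at least 2-fold changed, and 263 assembled isoforms, and 1 of 35 splits, the real one, gave a result as large for each, the highest other value being 0. Chance is not excluded for the number of gene lists called by camera with the preset correlation. The real groups gave 8 lists, 4 of 35 splits gave at least as many, and the highest other split gave 10.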
